A study of Mus musculus with 19 samples.

How the data were processed

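Per the labels, splenocytes or thymocytes of 3H9 transgenic C57BL/6 mice were stained and sorted, and because few cells were recovered each sample was mixed with 1000000 Rag-/- splenocytes, which hold no rearranged Igκ, as carrier for RNA isolation. Igκ cDNA was amplified with a degenerate Vκ forward primer and a Cκ reverse primer for 10 cycles, then for 20 cycles with adapters and a barcode, and read as single 150 bp reads on an Illumina HiSeq. There are 19 libraries: 7 of CD19+B220+IgM-IgD- thymic cells (switched), 7 of CD19+B220+IgM+IgD+ thymic cells (unswitched) and 5 of CD19+B220+ splenic cells. The labels number the libraries within each group and do not say whether a number marks one mouse in several groups. The aligner, error filters and germline annotation are not given in the sources used here.

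The authors deposited raw read counts per combination of Vκ gene, Jκ gene and CDR3 amino acid sequence, without normalization, 1 column per library. The authors' second table gives percent of a library's reads. It was checked against the counts, and all 419805 values agreed within 1e-09. The authors' last table, of top entries, holds 63 entries of the percent table, chosen by a rule that is not stated, for the thymic groups, with the mean percent of each thymic group as deposited. Its last column is the deposited ratio of the switched over the unswitched mean made by the authors, above 1 in 31 entries and below 1 in 32. All 882 of its percent values matched the percent table within the same tolerance. This table was used only for the ratios quoted by name. All tests started from the count table. Vκ names were compared with the gene names of a mouse reference table (assembly GRCm38.p6), used for names only: 92 of 93 matched, IGKV4-52 did not, and IGKV14-126, with 10739 reads (0.457% of all reads), is listed there as a pseudogene and was kept. Comments on functionality stood in 234 entries. A share of reads with a stop codon or frameshift had been planned and was not computed, since the files mark neither.

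Depth ran from 2137 to 345851 reads in switched thymic libraries (median 21806), from 2407 to 485614 in unswitched thymic libraries (median 27177) and from 133403 to 295916 in splenic libraries (median 219537). Of 22095 entries, 57.5% were seen in 1 library and 99 in all 19, and entries of a single read made up 50.3% to 56.9% of each library's entries. Replicate libraries of a group differed by more than counting error in every pair (lowest chi-square per degree of freedom 3.45). A share of 0 allows up to 3 reads of the total. Intervals of single shares are exact 95% binomial (Clopper-Pearson) intervals and cover counting error only, since reads from PCR without molecular identifiers are not independent molecules.

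The 3 comparisons were switched against unswitched thymic, switched thymic against splenic, and unswitched thymic against splenic libraries. Clonotypes, and reads summed per Vκ gene, were tested with edgeR 4.0.16 (quasi-likelihood fit with robust=TRUE) on all 19 libraries in 1 fit with group as the only term. Library sizes were the total reads, so that the test is one of shares of reads, and features were kept by filterByExpr with its defaults, which left 420 clonotypes and 76 Vκ genes. Adjusted p values are Benjamini-Hochberg with a threshold of 0.05, and a feature past it is called. Shares of each Vκ family, Jκ gene and position class were compared between libraries by two-sided exact permutation tests of the difference in means. Position classes use the position number in the Vκ name, which counts from the Jκ cluster: proximal up to 50, middle 51 to 100, distal above 100. The same test was used for CDR3 features weighted by reads (length, net charge as K and R minus D and E, shares with D or E, with K or R, and of the modal length of 11 residues with both anchors) and for 6 diversity measures on reads thinned once to 2137 with a fixed seed. Adjustment was over all features of the 3 comparisons together within each of these 3 families of tests. The smallest two-sided exact p is 0.000583 for 7 against 7 libraries and 0.00126 for 7 against 5. It is higher without the libraries under 10000 reads, and with 1 library left out of a comparison with spleen. A call that ends there can reflect fewer libraries alone. Similarity was the Morisita-Horn index of clonotype shares, with group labels permuted 100000 times or exactly enumerated. Similarity of same-numbered thymic libraries was tested one-sided over all 5040 pairings.

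The named features follow a rule. Clonotypes were, per comparison, the 5 with the largest rise and the 5 with the largest fall among those called and detected in most libraries of the higher group (4 of 7 or 3 of 5 at least), plus the 3 with the highest mean share in each group. Vκ genes were up to 8 rising and 8 falling with the smallest p among those called, plus the 8 with the highest mean share over all libraries. Vκ families were those over 5% in any group, and, chosen after their values were seen, IGKV17 and IGKV19, together with every Jκ gene, position class, CDR3 feature and diversity measure. Comparisons, lists, tests, this rule and the alternatives, apart from what is named here as chosen later, were fixed before the data were examined. Where the lower group had 0 reads, the fold is a bound from pooled shares with a floor of 3 reads over the group. With 1 to 3 reads it is the ratio of pooled shares with an exact 95% counting interval.

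The alternatives were TMM scaling, DESeq2 1.42.0 with poscounts size factors, limma 3.58.1 on log2 of reads per 1000000 plus 1, no low-count filter beyond 1 read in 2 libraries, robust=FALSE, a fit of the 2 groups alone, a block for replicate number, shares of distinct clonotypes, entries with at least 10 reads, no thinning, the Jaccard index, square root shares, and leaving out each library in turn. Leaving out IGKV5-43 reads, leaving out the 5 libraries under 10000 reads, and counting reads of YWQGTHFPRTF as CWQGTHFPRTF (both IGKV1-135 and Jκ1) were chosen after seeing the data. For each count from edgeR, 100 splits of the libraries into groups of the same sizes, the real one included, were tested alike. The models were also tested on simulated data. Among simulated clonotypes that passed the low-count filter, 16-fold changes were recovered in 79.5% to 87.1% of cases and 4-fold changes in 9.09% to 25.6%. Of unchanged ones 0.258% to 0.806% were called. Per comparison 59 to 73 clonotypes with 16-fold and 43 to 47 with 4-fold changes passed. Changed clonotypes that the filter removed are not counted, so recovery of all changes is lower. Among Vκ genes 100% and 80% were recovered, and 1.82% to 9.8% of unchanged genes were called. An Igκ amplicon holds no transcripts of other genes, so markers of other cell types could not be measured. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.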

Results

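The series profiled immunoglobulin kappa (Igκ) light chains of B cells sorted from 3H9 mice, C57BL/6 animals that carry a transgenic heavy chain with affinity for DNA. In such animals the light chain decides much of what the receptor binds, and light chains that veto DNA binding are known as editors. The files hold 19 libraries, made of 7 of class-switched thymic B cells (CD19+B220+IgM-IgD-), 7 of unswitched thymic B cells (CD19+B220+IgM+IgD+) and 5 of splenic B cells (CD19+B220+). Each entry, called a clonotype here, is a combination of Vκ gene, Jκ gene and CDR3 amino acid sequence, the CDR3 being the loop formed at the V-J junction. The libraries held 2351072 reads in 22095 clonotypes of 93 Vκ genes, and 12710 clonotypes were seen in 1 library.

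Depth differed widely between libraries. The switched thymic libraries 1 to 7 held 21806, 44406, 7891, 142370, 345851, 6022 and 2137 reads. The unswitched thymic libraries 1 to 7 held 27177, 16055, 58647, 485614, 110613, 7433 and 2407 reads. The splenic libraries 1 to 5 held 282688, 295916, 219537, 133403 and 141099 reads. A count of 0 allowed a share of up to 0.140% in the shallowest library and up to 0.000618% in the deepest. The reads carried no molecular identifiers, so intervals and floors cover counting error alone. The number of cells sorted per library is not given in the sources used here.

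The first comparison asked how the light chains of class-switched thymic B cells differ from those of unswitched thymic B cells. IGKV5-43 took 23.0% ± 18.3 (SD, n = 7) of the reads of switched thymic libraries and 0.305% ± 0.221 (SD, n = 7) of those of unswitched thymic libraries. Its log2 fold change was 6.30 ± 0.65 (SE; adjusted p = 2.2e-08, edgeR), and 7 of 7 switched libraries lay above every unswitched one. The reference lists IGKV5-45 both as a synonym of IGKV5-43 and as a gene of its own, and 0 entries of the read table name IGKV5-45, so reads of this pair cannot be told apart. Of 8 IGKV8 genes tested 5 fell. IGKV8-19 held 1.75% ± 1.04 in switched and 5.97% ± 1.24 in unswitched libraries (SD, n = 7 each), a log2 fold change of -1.77 ± 0.36 (adjusted p = 0.00102). IGKV8-28 held 2.19% ± 1.90 against 7.79% ± 2.03, a log2 fold change of -1.83 ± 0.45 (adjusted p = 0.00301).

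**Figure D1:**
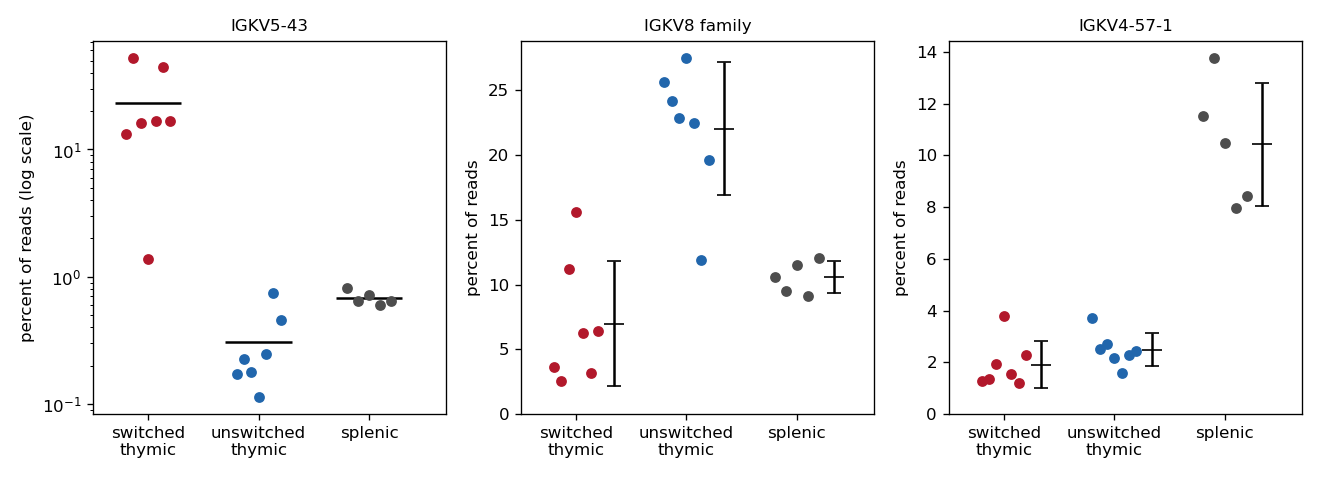
Percent of reads per library for IGKV5-43 (log axis, horizontal lines are means), the IGKV8 family and IGKV4-57-1 (linear axes, bars are mean ± SD) in 7 switched thymic, 7 unswitched thymic and 5 splenic libraries. IGKV5-43 averaged 23.0%, 0.305% and 0.680%, the IGKV8 family 6.97%, 22.1% and 10.6%, and IGKV4-57-1 1.92%, 2.49% and 10.4% in these groups.

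Of 76 Vκ genes tested, 4 rose and 17 fell in switched relative to unswitched thymic libraries. The other 3 that rose were IGKV5-48, IGKV10-96 and IGKV12-41. IGKV5-48 went from 0.0487% ± 0.0240 to 0.242% ± 0.191 (SD, n = 7 each; log2 fold change 2.32 ± 0.55, adjusted p = 0.00247). Of its 1052 reads in switched libraries, 336 carried the CDR3 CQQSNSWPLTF, which is also that of the leading IGKV5-43 clonotype. The rise of IGKV10-96 (log2 fold change 2.26 ± 0.75, adjusted p = 0.0228) lost its call without switched library 3 (1.36), unswitched library 4 (2.03) or the libraries under 10000 reads (1.78), with the 2 groups alone (2.25) and under limma (3.24). IGKV12-41 rested on 24 against 3 reads, a ratio of pooled shares of 9.93 (95% counting interval 3.01 to 51.5), and lost its call with any of 6 libraries left out, switched 1 and 3 and unswitched 1, 3, 4 and 5, under limma and without the libraries under 10000 reads. The ratio was 5.45 without switched library 3, 25.2 without switched library 5, 29.1 without unswitched library 2 and 3.12 without unswitched library 4. IGKV6-17 had 3 reads in switched and 81 in unswitched libraries, a 21.8-fold lower pooled share (95% counting interval 7.19 to 108) and a 47.1-fold lower mean share. The further named genes that fell were IGKV8-30 (log2 fold change -1.72 ± 0.37), IGKV1-99 (-1.81 ± 0.38), IGKV14-100 (-1.55 ± 0.34), IGKV4-51 (-2.60 ± 0.59) and IGKV4-55 (-1.48 ± 0.37), with adjusted p from 0.00102 to 0.00336. With a block for replicate number 62 genes were tested, of which 1 rose and 18 fell, so at most 1 of the 4 rises kept its call. The labels do not say that the numbers pair the libraries.

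By family, 2 of 4 IGKV5 genes tested rose and 0 fell (3 rose adjusted over the list alone). In the IGKV8 family 5 of 8 fell and 0 rose, with the same counts adjusted over the list alone and under TMM scaling. In the IGKV1 family 4 of 7 fell, of which 1 fell under TMM. Of 26 IGKV4 genes 4 fell and 0 rose, whereas under TMM 4 rose and 3 fell. In the IGKV3 family (Vκ21), which includes known editors of 3H9, 0 of 8 genes were called, and 1 rose under TMM. IGKV3-1 held 10.9% ± 6.39 in switched and 5.54% ± 1.67 in unswitched libraries (log2 fold change 0.98 ± 0.40, adjusted p = 0.0612 as shares of reads, 0.00597 under TMM). IGKV5-39 held 8.26% ± 3.74 against 4.27% ± 2.68 (0.95 ± 0.40, adjusted p = 0.0699 as shares of reads, 0.00551 under TMM). IGKV3-2 held 4.19% ± 4.13 against 11.2% ± 3.85 (-1.41 ± 0.54, adjusted p = 0.0519). By distance from the Jκ cluster, 3 of 31 proximal genes rose and 6 fell, 1 of 30 middle genes rose and 8 fell, and 0 of 15 distal genes rose and 3 fell. Under TMM the distal genes turned to 3 rising and 0 falling. IGKV5-43 reads lower every other share, and the median log2 fold change of the tested genes was -0.44 as shares of reads and 0.19 under TMM, with 15 rising and 11 falling under TMM.

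As mean shares per library, the IGKV5 family took 31.6% ± 17.2 of reads in switched and 4.74% ± 2.92 in unswitched thymic libraries (SD, n = 7 each; exact permutation test, adjusted p = 0.0216). The IGKV8 family took 6.97% ± 4.82 against 22.1% ± 5.11 (exact permutation test, adjusted p = 0.0162). The IGKV19 family, whose one measured gene IGKV19-93 is Vκ38C, an editor of 3H9, took 1.16% ± 0.472 against 2.43% ± 0.814 (exact permutation test, adjusted p = 0.0270). This family was singled out after its values were seen, and its call ended with IGKV5-43 reads left out (difference -0.846 percentage points), without the libraries under 10000 reads (-1.20) and by distinct clonotypes (-1.02). The IGKV5 call ended without the libraries under 10000 reads (25.7 percentage points) and the IGKV8 call by distinct clonotypes (-6.25). With all libraries the IGKV5 difference was 26.9 points. Its lost call says little of stability, since fewer libraries raise the smallest exact p possible. The IGKV1, IGKV3 and IGKV4 families took 11.3% ± 6.17, 24.7% ± 10.1 and 15.4% ± 6.27 in switched libraries, and 15.7% ± 2.60, 28.5% ± 4.79 and 18.2% ± 2.55 in unswitched ones (SD, n = 7), and were not called. Jκ1, Jκ2, Jκ4 and Jκ5 took 22.3% ± 18.6, 28.8% ± 10.8, 13.9% ± 6.24 and 35.0% ± 18.0 in switched libraries against 22.2% ± 1.24, 27.4% ± 1.07, 16.2% ± 0.943 and 34.2% ± 1.58, also without a call. Jκ3 had 1 read. Proximal, middle and distal genes took 67.8% ± 13.0, 16% ± 6.55 and 16.2% ± 6.77 against 59.3% ± 6.97, 21.4% ± 3.64 and 19.2% ± 4.19, not called.

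Among 420 clonotypes tested, 20 rose and 66 fell in switched relative to unswitched thymic libraries. The 5 with the largest rise were all of IGKV5-43. The Jκ5 clonotype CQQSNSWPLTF took 13.2% ± 15.3 against 0.126% ± 0.0581 (SD, n = 7 each; log2 fold change 6.75 ± 0.73, adjusted p = 2.9e-07) and lay above every unswitched library in 7 of 7. The authors' deposited table gives a ratio of 105 for it. The Jκ4 clonotype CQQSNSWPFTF rose by 6.01 ± 1.16 on the log2 scale. The Jκ1 clonotype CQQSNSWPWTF (log2 fold change 8.45 ± 2.76, adjusted p = 0.0379) rested on switched library 6, where it took 37.5% of reads (exact 95% interval 36.3 to 38.7), and without it the value was 2.77 and not called. It also lost its call without any of the unswitched libraries 1 to 5 (7.99 to 8.16), without a low-count filter (8.18) and under limma (3.65). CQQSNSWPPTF and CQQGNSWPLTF, both with Jκ5, differ from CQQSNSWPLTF in 1 residue, and whether they are clones or misreads of it is not known. They had 253 and 192 reads in switched libraries and 1 read each in unswitched ones. This gives pooled ratios of 314 (95% counting interval 55.8 to 12449) and 238 (42.3 to 9459). The ratios of their mean shares were only 37.2 and 49.7, since the reads came from unswitched libraries 6 and 2, with 7433 and 16055 reads in all. Without the deepest unswitched library, 4, the pooled ratios were 98.6 and 74.8, and without the library that held the read, with 0 reads left, they were at least 104 and at least 77.6. IGKV3-1 with Jκ2 and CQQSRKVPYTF took 8.16% ± 5.24 against 1.30% ± 0.316 (log2 fold change 2.65 ± 0.42, adjusted p = 2.3e-04), higher in 7 of 7, and the authors' ratio is 6.27.

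The 5 clonotypes with the largest fall had 0 reads in the switched thymic libraries. Against a floor of 3 reads over the group, pooled shares were at least 82.5-fold lower for IGKV8-24 Jκ4 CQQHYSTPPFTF and 42.7-fold for IGKV8-24 Jκ2 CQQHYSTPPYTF. They were at least 40.0-fold lower for IGKV4-51 Jκ5 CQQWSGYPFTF and 34.7-fold for IGKV1-132 Jκ4 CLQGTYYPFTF. Without switched library 5, the deepest of its group, these bounds were 32.5, 16.8, 15.8 and 13.6. The bound for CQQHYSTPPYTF was 76.1 without unswitched library 4, and that for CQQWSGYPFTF was 110.3 without unswitched library 4 and 26.7 without unswitched library 3. IGKV4-57-1 Jκ5 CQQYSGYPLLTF was at least 103-fold lower, but 369 of its 385 reads came from unswitched library 4, without which the bound was 13.7 (40.7 without switched library 5), and DESeq2 did not call it. IGKV8-19 Jκ5 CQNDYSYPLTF fell from 2.48% ± 0.530 to 0.482% ± 0.302 (log2 fold change -2.37 ± 0.44, adjusted p = 4.9e-04). The 2 IGKV3-2 clonotypes with the highest shares in unswitched libraries, Jκ2 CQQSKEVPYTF (3.92% ± 1.51 there, 1.31% ± 2.05 in switched) and Jκ1 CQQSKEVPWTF (2.85% ± 1.67 and 0.815% ± 1.03), were not called (adjusted p = 0.113 and 0.0629). TMM scaling gave 25 rising and 29 falling clonotypes, with a median log2 fold change of 0.14 in place of -1.01. With the 2 groups fitted alone 9 rose and 24 fell, without a low-count filter 138 rose and 201 fell, and without the 5 libraries under 10000 reads 19 rose and 128 fell.

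Switched thymic libraries were less diverse in their reads. Thinning evens out reads and not cells, and the number of cells sorted is not given. An effect of cell number on these measures therefore cannot be told apart in any comparison. With every library thinned to 2137 reads, switched libraries held 306 ± 43.2 clonotypes and unswitched ones 428 ± 31.9 (SD, n = 7 each). Shannon entropy was 4.03 ± 0.717 against 5.15 ± 0.154, and the inverse Simpson index 22.2 ± 15.0 against 89.7 ± 17.3. The Gini coefficient was 0.747 ± 0.0551 against 0.652 ± 0.0213. The leading clonotype took 21.2% ± 13.8 against 4.33% ± 1.28, and the leading 10 took 53.5% ± 14.8 against 25.3% ± 4.01. All 6 measures differed with adjusted p = 0.00175 by exact permutation test, and in each the groups did not overlap, for which 0.000583 is the smallest two-sided p possible. Without thinning, the numbers of clonotypes and the Gini coefficients (difference 0.0328) were not called, and the numbers of clonotypes also lost their call among entries with at least 10 reads (difference -65.9).

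CDR3s of switched thymic libraries carried an aspartate or glutamate in 21.7% ± 8.97 of reads, against 41.4% ± 5.18 in unswitched ones (SD, n = 7 each; exact permutation test, adjusted p = 0.0262), lower in 6 of 7 than in every unswitched library. Their mean net charge was 0.0133 ± 0.207 against -0.245 ± 0.0524 (exact permutation test, adjusted p = 0.0442). By distinct clonotypes neither was called (-5.17 percentage points and 0.0461). With IGKV5-43 reads left out, 0 of 5 CDR3 features were called, and the acidic share then differed by -11.9 percentage points (exact permutation test, p = 0.0385 before adjustment). The charge difference (0.259) also lost its call without switched library 1, 3, 5 or 7 or unswitched library 1, 2 or 4 (values over the single libraries left out 0.215 to 0.318). Reads with lysine or arginine (22.4% ± 8.90 against 23.0% ± 3.36), mean length (11.03 ± 0.0432 against 11.01 ± 0.0119 residues, anchors included) and the share of the 11-residue length (92.3% ± 4.02 against 90.5% ± 0.889) were not called.

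**Figure D2:**
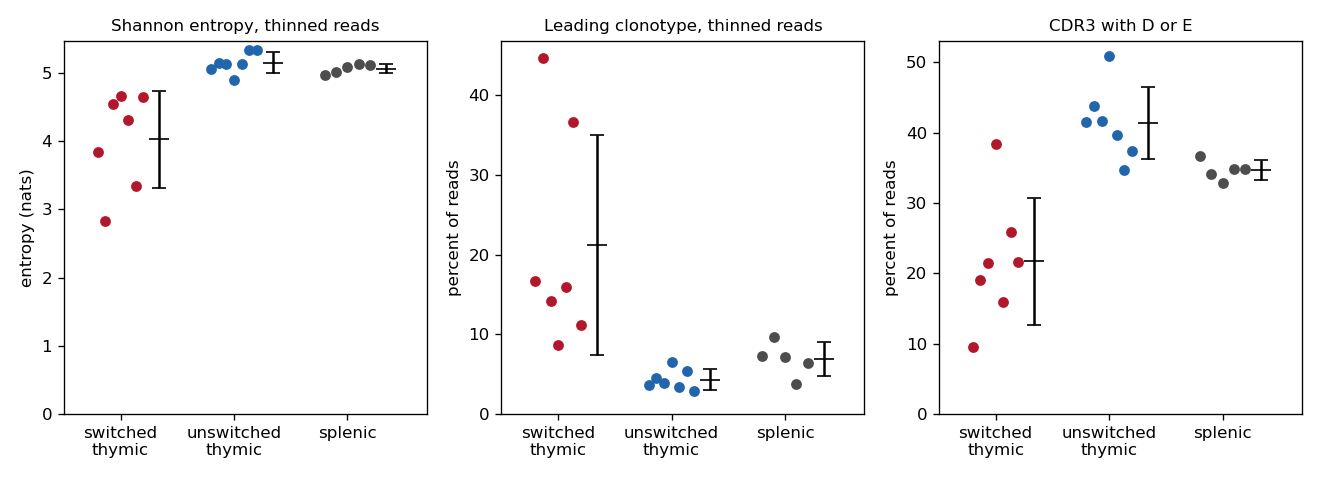
Shannon entropy and leading clonotype share after thinning to 2137 reads, and percent of reads whose CDR3 holds aspartate or glutamate, per library (points) with mean ± SD (bars), in 7 switched thymic, 7 unswitched thymic and 5 splenic libraries. Entropy averaged 4.03, 5.15 and 5.07, the leading clonotype 21.2%, 4.33% and 6.91%, and the acidic share 21.7%, 41.4% and 34.7%.

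The second comparison set switched thymic against splenic B cells. The labels name no IgM or IgD gate for the splenic cells. Organ and sort gate therefore cannot be told apart here or in the third comparison. IGKV5-43 was again higher, at 23.0% ± 18.3 (SD, n = 7) against 0.680% ± 0.0843 (SD, n = 5; log2 fold change 5.08 ± 0.71, adjusted p = 7.7e-06), and above every splenic library in 7 of 7. IGKV3-1 rose, with 10.9% ± 6.39 against 3.04% ± 1.08 (1.84 ± 0.46, adjusted p = 0.0029). IGKV4-57-1 fell, with 1.92% ± 0.922 against 10.4% ± 2.38 (-2.44 ± 0.37, adjusted p = 1.4e-05), below every splenic library in 7 of 7. IGKV17-121, a Vκ20 gene, fell, with 0.524% ± 0.331 against 2.59% ± 0.507 (-2.35 ± 0.45, adjusted p = 2.2e-04).

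Of the 76 Vκ genes, 3 rose and 18 fell in switched thymic relative to splenic libraries, and under TMM 12 rose and 14 fell (median log2 fold change -0.58 as shares of reads, 0.04 under TMM). The third gene that rose, IGKV4-52 (2.13 ± 0.76, adjusted p = 0.0333), lost its call without switched library 4 (1.27) or splenic library 1, 3, 4 or 5 (1.99 to 2.10) and was not called with the 2 groups alone (2.11) or under limma (0.15). IGKV6-17 had 3 against 221 reads, a 39.2-fold lower pooled share (95% counting interval 13.2 to 191), 25.5-fold without splenic library 4, and a 63.6-fold lower mean share. IGKV8-34 (-5.57 ± 1.01), IGKV4-62 (-4.51 ± 0.89), IGKV4-63 (-2.44 ± 0.57), IGKV8-30 (-1.92 ± 0.39) and IGKV1-99 (-1.81 ± 0.41) also fell. By family, 3 of 7 IGKV1 genes fell and 0 rose, 3 of 8 IGKV8 genes fell and 0 rose (3 and 1 under TMM), 1 of 4 IGKV5 genes rose, and 1 of 26 IGKV4 genes rose and 5 fell (4 and 4 under TMM). Of 2 IGKV17 genes 1 fell, and 2 fell adjusted over the list alone. Of 8 IGKV3 genes 1 rose and 1 fell, and 2 rose and 0 fell under TMM. By position, 2 of 31 proximal genes rose and 7 fell, 1 of 30 middle genes rose and 8 fell, and 3 of 15 distal genes fell (6 and 6, 4 and 5, 2 and 3 under TMM).

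Among clonotypes, 20 rose and 92 fell relative to spleen (26 and 49 under TMM, median log2 fold change -0.86 as shares of reads and -0.21 under TMM, 214 and 203 without a low-count filter, 9 and 163 under limma, and 25 and 174 without the 5 libraries under 10000 reads). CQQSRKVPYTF of IGKV3-1 and Jκ2 took 8.16% ± 5.24 (SD, n = 7) against 0.499% ± 0.175 (SD, n = 5; log2 fold change 4.03 ± 0.52, adjusted p = 1.0e-05), and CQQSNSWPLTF of IGKV5-43 and Jκ5 took 13.2% ± 15.3 against 0.232% ± 0.0848 (5.83 ± 0.81, adjusted p = 1.9e-05). IGKV5-43 Jκ5 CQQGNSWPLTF (5.84 ± 1.45) and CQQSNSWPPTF (5.52 ± 1.34), IGKV3-1 Jκ2 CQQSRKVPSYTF (5.26 ± 1.08) and IGKV5-43 Jκ4 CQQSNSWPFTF (4.35 ± 1.18, not called by limma) rose too. Whether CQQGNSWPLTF and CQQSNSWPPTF are misreads of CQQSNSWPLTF was not tested. With 0 reads in switched libraries, pooled shares were at least 73.6-fold lower for IGKV4-51 Jκ5 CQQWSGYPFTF, 43.8-fold for IGKV1-135 Jκ2 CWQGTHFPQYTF and 41.3-fold for IGKV4-79 Jκ2 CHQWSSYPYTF. Without switched library 5 these bounds were 29.0, 17.2 and 16.3, and that for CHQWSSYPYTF was 23.8 without splenic library 1. IGKV4-57-1 Jκ5 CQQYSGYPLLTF was at least 47.0-fold lower, but 247 of its 265 splenic reads came from splenic library 3, without which the bound was 4.01 (18.5 without switched library 5), and DESeq2 did not call it. IGKV1-110 Jκ2 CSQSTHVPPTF had 1 against 974 reads, a ratio of 518 (95% counting interval 92.8 to 20481), 204 without switched library 5 and, with 0 reads left, at least 129.6 without switched library 4. The ratio of its mean shares was 1102. The clonotype with the highest mean share in spleen, IGKV4-57-1 Jκ5 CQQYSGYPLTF, took 1.16% ± 0.745 against 6.71% ± 1.95 (-2.53 ± 0.41, adjusted p = 1.9e-04). IGKV1-135 Jκ1 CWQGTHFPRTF (-1.30 ± 0.43) was not called under TMM, DESeq2, without a filter, with the 2 groups alone, with IGKV5-43 reads left out, or without splenic library 3 or 5 (-1.14 and -1.32). Its fall also depends on how an entry that differs in the first residue, YWQGTHFPRTF, is read. Counted as 1 clonotype, the 2 took 3.36% ± 6.58 against 2.45% ± 0.612 and the log2 fold change was 0.46 (adjusted p = 0.690). Whether that entry, which led switched library 1, is a misread of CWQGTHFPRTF or a clone of its own is not known. IGKV3-4 Jκ2 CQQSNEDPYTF (-1.81 ± 0.60) was not called under TMM, DESeq2, without a filter, with the 2 groups alone, without the libraries under 10000 reads, or without splenic library 2 (-1.02).

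In mean shares, 12 families, Jκ genes or position classes differed between switched thymic and splenic libraries. Among these, the IGKV2 (0% against 0.00110%) and IGKV11 families (0.000248% against 0.00403%) lie under what a count of 0 allows in shallow switched libraries (up to 0.140%). For these families depth cannot be told apart as the source. The IGKV5 family took 31.6% ± 17.2 (SD, n = 7) against 5.42% ± 0.511 (SD, n = 5; exact permutation test, adjusted p = 0.0270), and proximal genes took 67.8% ± 13.0 against 42.4% ± 3.19 (exact permutation test, adjusted p = 0.0292). The IGKV1 family took 11.3% ± 6.17 against 22.4% ± 2.52 (exact permutation test, adjusted p = 0.0338) and the IGKV4 family 15.4% ± 6.27 against 24.3% ± 2.50 (exact permutation test, adjusted p = 0.0486). Middle genes took 16% ± 6.55 against 27.9% ± 3.46 and distal genes 16.2% ± 6.77 against 29.7% ± 2.91 (exact permutation tests, adjusted p = 0.0309 and 0.0259). The IGKV8 family, at 6.97% ± 4.82 and 10.6% ± 1.25, was not called (exact permutation test, adjusted p = 0.309), nor were the IGKV3 family or the Jκ genes. The IGKV17 family, singled out after its values were seen, took 1.06% ± 0.620 against 3.90% ± 0.766 (exact permutation test, adjusted p = 0.0162). The IGKV19 family, also singled out afterwards, took 1.16% ± 0.472 against 2.31% ± 0.196 (exact permutation test, adjusted p = 0.0216), below every splenic library in 7 of 7, and its call ended by distinct clonotypes (-0.589 percentage points). The IGKV1, IGKV4, IGKV5, IGKV19 and position class calls ended with IGKV5-43 reads left out, and 4 features were then called. Those of IGKV1, IGKV4 and the position classes also ended without the libraries under 10000 reads, and those of IGKV4 (-0.904) and middle genes (-3.33) by distinct clonotypes. Calls also ended with single libraries left out: IGKV5 without any splenic library (22.2 to 30.5 percentage points over all libraries left out), IGKV1 without splenic 3, 4 or 5 (-13.2 to -10.1), IGKV4 without any library but switched 1 (-10.8 to -7.53), proximal and distal genes without splenic 3 (22.7 to 29.2 and -15.2 to -12.1), and middle genes without splenic 1, 2, 3 or 5 (-14.0 to -10.7).

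Relative to spleen, switched thymic libraries also held fewer clonotypes at 2137 reads, 306 ± 43.2 (SD, n = 7) against 431 ± 4.32 (SD, n = 5; exact permutation test, adjusted p = 0.00284). Shannon entropy was 4.03 ± 0.717 against 5.07 ± 0.0697 and the inverse Simpson index 22.2 ± 15.0 against 68.9 ± 14.4 (exact permutation tests, adjusted p = 0.0136 and 0.00284). The Gini coefficient was 0.747 ± 0.0551 against 0.666 ± 0.00748 (exact permutation test, adjusted p = 0.0165), but without thinning its difference turned to -0.0661, and among entries with at least 10 reads it was not called (0.0681). The leading clonotype took 21.2% ± 13.8 against 6.91% ± 2.11 (exact permutation test, adjusted p = 0.0437), a call lost without any 1 splenic library (10.3 to 16.3 percentage points over all libraries left out). The leading 10 took 53.5% ± 14.8 against 28.0% ± 2.36 (exact permutation test, adjusted p = 0.0126). Acidic CDR3s made up 21.7% ± 8.97 against 34.7% ± 1.42 of reads, and mean net charge was 0.0133 ± 0.207 against -0.299 ± 0.0736 (exact permutation tests, adjusted p = 0.0442 for both). Both CDR3 calls ended with IGKV5-43 reads left out and by distinct clonotypes (-3.10 percentage points and 0.0637), and the acidic share also without the libraries under 10000 reads. The acidic share also lost its call without any library but switched 4 or 6 (-15.8 to -11.0 percentage points), and the charge without any but switched 6 (0.269 to 0.372). Lysine or arginine content, length and the share of the 11-residue length were not called.

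The third comparison set unswitched thymic against splenic B cells. IGKV8-24 was higher in unswitched thymic libraries, at 5.65% ± 1.60 (SD, n = 7) against 1.2% ± 0.416 (SD, n = 5; log2 fold change 2.23 ± 0.47, adjusted p = 0.00135), above every splenic library in 7 of 7. In switched thymic libraries it held 1.90% ± 1.30 (SD, n = 7), a mean between those of unswitched thymic and splenic libraries. Of 8 IGKV8 genes 0 were called higher in switched thymic than in splenic libraries as shares of reads, and 1 was under TMM. Whether the higher share is common to both thymic groups is therefore not settled. IGKV4-57-1 was lower in unswitched thymic than in splenic libraries, at 2.49% ± 0.644 against 10.4% ± 2.38 (-2.07 ± 0.36, adjusted p = 3.8e-04). Both Vκ20 genes fell: IGKV17-121 held 0.503% ± 0.276 against 2.59% ± 0.507 (-2.38 ± 0.44, adjusted p = 4.3e-04) and IGKV17-127 held 0.254% ± 0.210 against 1.32% ± 0.288 (-2.48 ± 0.55, adjusted p = 0.00183). IGKV5-43 held 0.305% ± 0.221 against 0.680% ± 0.0843 and was not called (-1.22 ± 0.57, adjusted p = 0.144).

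Of the 76 Vκ genes, 3 rose and 11 fell in unswitched thymic relative to splenic libraries, 2 and 11 under TMM (median log2 fold change -0.03 and -0.06), and 11 and 16 with the 2 groups alone. IGKV4-74 rose (1.68 ± 0.47, adjusted p = 0.0117). IGKV3-12 (1.95 ± 0.68, adjusted p = 0.0425) was not called under TMM or limma, without a filter or with IGKV5-43 reads left out, nor without unswitched library 2, 3, 4 or 6 or any splenic library (1.86 to 2.02). IGKV4-72 (-4.04 ± 0.87), IGKV4-62 (-2.86 ± 0.80), IGKV5-48 (-2.19 ± 0.57) and IGKV14-111 (-1.96 ± 0.55) fell, and IGKV12-41 had 3 against 443 reads, a 97.5-fold lower pooled share (95% counting interval 33.1 to 474). That was 286-fold without unswitched library 2 and 30.6-fold without unswitched library 4, and the mean share was 21.3-fold lower. By family, 2 of 2 IGKV17 genes fell, 1 of 8 IGKV8 genes rose and 1 fell (3 and 2 adjusted over the list alone), 1 of 26 IGKV4 genes rose and 3 fell, and 1 of 4 IGKV5 genes fell. Of 8 IGKV3 genes 1 rose (0 adjusted over the list alone, and 0 under TMM), and 0 of 7 IGKV1 genes were called. By position, 2 of 31 proximal genes rose and 4 fell (1 and 4 under TMM), 1 of 30 middle genes rose and 4 fell, and 3 of 15 distal genes fell.

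Among clonotypes, 11 rose and 11 fell, and 6 rose and 16 fell under TMM (median log2 fold change 0.13 as shares of reads, -0.31 under TMM). With the 2 groups fitted alone 45 rose and 39 fell, DESeq2 gave 20 and 29, and the libraries at or over 10000 reads gave 11 and 28. Leaving out each splenic library in turn gave 9, 11, 8, 9 and 14 calls. The IGKV8-24 CDR3 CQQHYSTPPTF rose with Jκ1 (0.482% ± 0.237, n = 7, against 0.0124% ± 0.00879, n = 5; 5.26 ± 0.94, adjusted p = 0.00124), Jκ4 (4.63 ± 1.05) and Jκ5 (3.32 ± 0.75). IGKV14-130 Jκ1 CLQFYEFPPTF (4.36 ± 1.15) and IGKV4-53 Jκ5 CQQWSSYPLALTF, at least 24.2-fold higher with 0 splenic reads (74.0 without unswitched library 4, 4.79 without 5, which held 40 of its 48 reads), lost their calls without any 1 splenic library (4.15 to 4.72 for the former), under limma and without a filter. The leading splenic clonotype, IGKV4-57-1 Jκ5 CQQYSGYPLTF, took 0.861% ± 0.189 against 6.71% ± 1.95 (-2.96 ± 0.42, adjusted p = 4.6e-05). IGKV17-127 Jκ2 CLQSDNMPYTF fell (-3.00 ± 0.67, adjusted p = 0.00892). IGKV17-127 Jκ4 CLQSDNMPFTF (-4.37 ± 1.30), IGKV7-33 Jκ5 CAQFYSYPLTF (-5.14 ± 1.48), IGKV4-57-1 Jκ1 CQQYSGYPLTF (-3.91 ± 1.10) and IGKV5-48 Jκ5 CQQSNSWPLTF (-3.76 ± 1.02) fell with adjusted p from 0.0259 to 0.0437. Each of these 4 lost its call with most single libraries left out, in 11, 10, 9 and 8 of 12 cases. Without a low-count filter these 4, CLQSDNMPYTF and the Jκ5 form of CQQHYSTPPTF were not called, nor was its Jκ4 form under limma.

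In mean shares, 11 features differed between unswitched thymic and splenic libraries. Among these, the IGKV2 family (8.83e-05% against 0.00110%) lies under what a count of 0 allows in shallow unswitched libraries (up to 0.125%). Depth cannot be told apart as its source. The IGKV8 family took 22.1% ± 5.11 (SD, n = 7) against 10.6% ± 1.25 (SD, n = 5; exact permutation test, adjusted p = 0.0259) and proximal genes 59.3% ± 6.97 against 42.4% ± 3.19 (exact permutation test, adjusted p = 0.0216). The IGKV17 family took 0.757% ± 0.436 against 3.90% ± 0.766 (exact permutation test, adjusted p = 0.0162). The IGKV1 and IGKV4 families took 15.7% ± 2.60 and 18.2% ± 2.55 against 22.4% ± 2.52 and 24.3% ± 2.50 (exact permutation tests, adjusted p = 0.0270 and 0.0259), and IGKV1 lost its call without splenic library 3 (-7.55 to -6.06 over all libraries left out). Distal genes took 19.2% ± 4.19 against 29.7% ± 2.91 (exact permutation test, adjusted p = 0.0259). Middle genes (21.4% ± 3.64 against 27.9% ± 3.46) and Jκ5 (34.2% ± 1.58 against 30.9% ± 2.17) were called by exact permutation test (adjusted p = 0.0389 and 0.0292). They lost the call with 9 and 7 of 12 single libraries left out, at -7.59 to -5.34 and 2.74 to 3.86 percentage points. The IGKV3 and IGKV5 families and the other Jκ genes were not called, nor was the IGKV19 family (2.43% ± 0.814 against 2.31% ± 0.196; exact permutation test, adjusted p = 0.955). Counting distinct clonotypes in place of reads, the differences of the IGKV4 family and of middle genes turned to 0.886 and 0.412 percentage points, and the IGKV1, IGKV8, Jκ5 and proximal calls ended (-2.79, 4.28, 1.68 and 5.75).

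The diversity of unswitched thymic and splenic libraries differed in 1 of 6 measures, the leading clonotype, at 4.33% ± 1.28 (SD, n = 7) against 6.91% ± 2.11 (SD, n = 5; exact permutation test, adjusted p = 0.0398). That call was lost with 8 of 12 single libraries left out (-3.35 to -1.88 percentage points), without thinning (-2.22) and without the libraries under 10000 reads (-2.15). Acidic CDR3s made up 41.4% ± 5.18 against 34.7% ± 1.42 of reads and CDR3s with lysine or arginine 23.0% ± 3.36 against 16.6% ± 1.48 (exact permutation tests, adjusted p = 0.0442 for both). Both calls were lost with IGKV5-43 reads left out (6.56 and 6.37 percentage points), by distinct clonotypes (2.07 and 1.87), and with 10 and 8 of 12 single libraries left out (5.09 to 7.80 and 5.63 to 7.32 percentage points). Net charge, length and the share of the 11-residue length were not called.

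**Figure D3:**
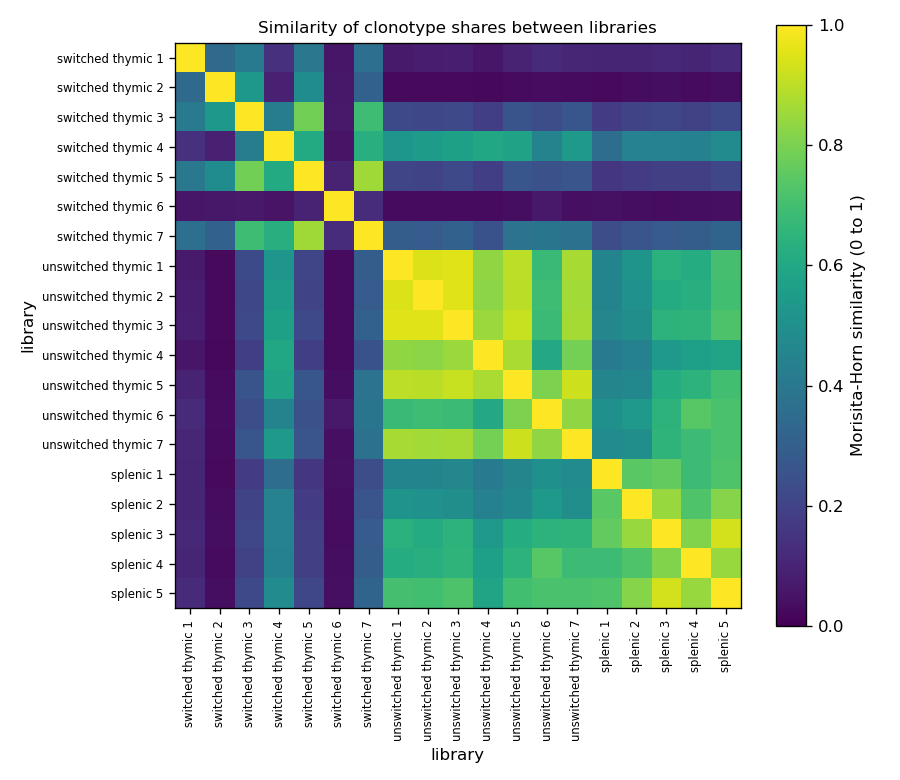
Morisita-Horn similarity of clonotype shares (0 to 1) between all pairs of the 19 libraries, ordered by group. Pairs of unswitched thymic libraries averaged 0.835, pairs of splenic libraries 0.789 and pairs of switched thymic libraries 0.360.

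On average, libraries of a group resembled each other more than libraries of other groups, and 18 of 19 were on average most similar to their own group. The exception, switched thymic library 4, had a mean similarity of 0.325 to its own group, 0.543 to unswitched thymic and 0.433 to splenic libraries. The mean Morisita-Horn similarity was 0.835 ± 0.0979 within unswitched thymic libraries, 0.789 ± 0.0739 within splenic and 0.360 ± 0.258 within switched thymic libraries (SD over pairs). Between groups it was 0.583 ± 0.0993 for unswitched thymic and splenic, 0.212 ± 0.175 for switched and unswitched thymic, and 0.183 ± 0.135 for switched thymic and splenic libraries. The mean within groups exceeded that between groups by 0.322 (permutation test over 100000 permutations, p = 1e-05, the smallest they can give). The excess was 0.385 for switched and unswitched thymic libraries, 0.315 for switched thymic and splenic, and 0.238 for unswitched thymic and splenic (exact permutation tests, p = 0.000583, 0.00253 and 0.00126). With the Jaccard index of clonotypes of at least 10 reads, the excess of switched and unswitched thymic libraries was 0.0141 and not called (exact permutation test, p = 0.182). Switched and unswitched thymic libraries of the same replicate number had a similarity of 0.233 and those of different numbers 0.209, a difference of 0.0240 (exact one-sided test over 5040 pairings, p = 0.00873). Without the replicate 4 library of either group it was 0.0116 and no longer called. By this index 3 of 7 switched and 1 of 7 unswitched libraries were most similar to their own number in the other thymic group. With group means removed, 5 of 7 switched and 7 of 7 unswitched libraries correlated best with their own number. The same-number difference was 0.0775 by the Jaccard index and 0.0296 by square root shares (exact one-sided tests, p = 0.00754 and 0.000794). The main tests treat the libraries as unpaired. The labels do not say what the replicate numbers mark.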

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

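Of the tests weighed here, those of the IGKV8 family for acidic CDR3s and of depth for shared rare clonotypes were set before their results were seen. The tests on splits, on IGKV5-43 (leading clonotypes, spill-over, scaling), on dilution by IGKV5-43 and on carry-over were chosen after the results, or examples of them, had been seen.

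IGKV5-43 was higher in switched than in unswitched thymic libraries in 7 of 7. A single expanded clonotype per library as the whole cause is argued against: with each library's leading IGKV5-43 clonotype removed, the gene still took 4.78% ± 3.24 against 0.179% ± 0.186 of reads (SD, n = 7 each; exact p = 0.000583, at most 0.00408 with any 1 library left out). Entries that differ from the leading one in 1 residue stayed in this remainder, and misreads among them were not tested. Spill-over of reads from 1 switched library into all the others is argued against by the Jκ partners of IGKV5-43. Jκ1 made up 86.9% of its reads in switched library 6 (exact 95% interval 85.5 to 88.1) and 0.108% in library 2 (0.0698 to 0.159). Switched libraries 1, 2, 3 and 5 all held mostly Jκ5, in 83.3%, 92.9%, 96.7% and 78.2% of these reads. They differed in Jκ2 (0.0347%, 6.79%, 2.34% and 15.0%) and Jκ4 (16.4%, 0.190%, 1.01% and 6.35%). A mix of a library's own reads and spilled ones could also differ so, and these values cannot decide on spill-over of part of the reads among some of the libraries. Scaling to total reads as the cause is argued against by TMM, under which the log2 fold change was 7.32. Reads shared with the near-identical IGKV5-45 were not tested, and a biological difference that goes with switching may account for the rise as a hypothesis.

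Acidic CDR3s were rarer in switched than in unswitched thymic libraries by 19.7 percentage points. A lower share of the IGKV8 family is argued against as the whole cause: without IGKV8 reads the difference was -16.4 points (19.3% ± 8.44 against 35.7% ± 6.12; exact p = 0.00291, at most 0.00583 with any 1 library left out). Dilution by IGKV5-43 reads cannot be told apart from a wider change: without them the difference was -11.9 points (29.5% ± 12.7 against 41.5% ± 5.13), and its exact p was 0.0385, but 0.00758 to 0.0781 with 1 library left out. The acidic share is not independent of Vκ usage. In the authors' list of top entries, those of IGKV3-2 and IGKV8-28 all hold D or E, whichever the Jκ gene. Other changes of Vκ usage were not tested as its source.

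Thymic libraries of the same number shared 55 of the 123 rare clonotypes, those with at least 10 reads in exactly 1 switched and exactly 1 unswitched library, where 41.7 were expected from the margins (ratio 1.32; exact p = 0.00476 over 5040 pairings, 0.0583 without number 4 and 0.00833 to 0.0417 without any other). Depth cannot be told apart, since the ratio stayed under the bound of 1.5 set for it while the exact p was low, and the deepest numbers 4 and 5 held 34 and 19 of the 55, number 3 held 2 and the others 0, with more (43) shared by switched library 5 and unswitched library 4. Carry-over in 1 direction, at 1 rate per pair, is argued against as the whole cause: 44 of the 55 had more reads in the unswitched library than the leading clonotype of the switched library allows (24 of 34 for number 4, 18 of 19 for number 5), and 36 had more in the switched library than that of the unswitched library allows (20 of 34 and 14 of 19; Poisson tests, adjusted p under 0.05). Since 25 were over both levels, carry-over in both directions at once stays open for the other 30, as does uneven amplification of carried templates, which was not tested. Shared mice or a shared preparation may be marked by the number, which the labels do not state.

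For clonotypes, chance is an unlikely source of the counts of all 3 comparisons, though 100 splits cannot exclude it. Of 100 splits of the switched and unswitched thymic libraries 1, the real one, gave as many calls (86, highest other 38). So did 1 of 100 for switched thymic and splenic libraries (112, highest other 71) and 1 of 100 for unswitched thymic and splenic libraries (22, highest other 15). For Vκ genes, 1 of 100 splits of the thymic libraries gave as many (21, highest other 12). The same held for 1 of 100 splits of unswitched thymic and splenic libraries (14, highest other 2). For switched thymic and splenic libraries it was 2 of 100 (21, highest other 21). Another split thus gave as many calls as the real one, so chance is not excluded there.

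The results below are values of single libraries that a test for a value apart from its group picked out. Among 258 groups of values checked 48 held one, where chance gives about 1 in 20. Reads in total stood apart in switched library 5 (345851) and unswitched library 4 (485614).

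In switched library 1 the IGKV1 family took 23.5% of reads, IGKV1-135 took 21% and IGKV5-48 took 0.656%. Also in this library, 18.2% of reads had a CDR3 that does not run from C to F, a feature outside the comparisons, against at most 1.55% in any other library (switched library 2) and 0.866% in a splenic one. Its leading clonotype was IGKV1-135 Jκ1 YWQGTHFPRTF with 16.6% of reads (exact 95% interval 16.1 to 17.1). Whether this entry is a clone or a misread of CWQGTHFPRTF, from which it differs in the first residue, is not known. If it is a misread, the 16.6% and the CDR3s not running from C to F belong mostly to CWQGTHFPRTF. In switched library 2, IGKV5-43 Jκ5 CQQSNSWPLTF took 45.9%. In switched library 3, IGKV10-96 took 0.950%. In switched library 6, Jκ1 took 62.2% and IGKV5-43 Jκ1 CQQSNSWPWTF took 37.5%. In switched library 7, IGKV17-121 took 1.17% and IGKV4-63 took 0.468%.

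Switched library 4 stood apart most often. There IGKV8-28 took 6.03%, IGKV4-52 took 0.644% and IGKV4-57-1 took 3.81%. Its clonotypes IGKV3-1 Jκ2 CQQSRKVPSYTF, IGKV3-2 Jκ2 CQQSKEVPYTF, IGKV3-2 Jκ1 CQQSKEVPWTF, IGKV4-57-1 Jκ5 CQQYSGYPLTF and IGKV3-4 Jκ2 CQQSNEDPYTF took 4.13%, 5.85%, 3.05%, 2.77% and 2.27%.

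In unswitched library 2, IGKV4-52 took 0.218% and IGKV8-24 Jκ2 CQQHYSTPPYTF took 0.187%. In unswitched library 4, IGKV14-100 was low at 0.404%, IGKV3-2 took 19.1% and IGKV3-2 Jκ1 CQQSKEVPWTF took 6.29%. In unswitched library 6, distal genes took 27.8%, IGKV10-96 took 0.202% and IGKV14-111 took 2.15%.

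In splenic library 1, CDR3s with lysine or arginine were low at 14.1% and the Gini coefficient was high at 0.679. In splenic library 2, IGKV8-24 Jκ5 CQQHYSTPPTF took 0.311% and IGKV3-4 Jκ2 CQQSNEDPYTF took 6.41%. In splenic library 3, IGKV4-57-1 Jκ5 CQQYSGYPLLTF took 0.113% and IGKV1-135 Jκ1 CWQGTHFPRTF took 3.52%. In splenic library 4, IGKV6-17 took 0.0712%. In splenic library 5, IGKV5-43 Jκ1 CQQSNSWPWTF took 0.0886% and IGKV8-24 Jκ2 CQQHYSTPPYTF took 0.0404%.

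Other values were picked out by the same test, but the reads do not show that their libraries stand apart. They rest on 1 to 3 reads, or lie under the share that a count of 0 allows in another library of the group (up to 0.140% in switched and 0.125% in unswitched libraries). With 1 to 3 reads these were IGKV6-17 in switched library 2 (0.00225%), IGKV1-110 Jκ2 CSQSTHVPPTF in switched library 4 (0.000702%), IGKV4-72 and IGKV17-127 Jκ4 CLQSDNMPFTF in switched library 7 (0.0468% and 0.140%), IGKV12-41 and IGKV5-43 Jκ5 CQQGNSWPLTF in unswitched library 2 (0.0125% and 0.00623%), and IGKV5-43 Jκ5 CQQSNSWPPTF and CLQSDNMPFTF in unswitched library 6 (0.0135% and 0.0404%). With more reads they were IGKV12-41 in switched library 3 (0.139%), IGKV14-130 Jκ1 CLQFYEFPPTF in switched library 4 (0.0513%), IGKV8-34 in switched library 5 (0.00173%) and IGKV7-33 Jκ5 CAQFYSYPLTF in unswitched library 6 (0.0673%).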

How the results depend on the processing

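The alternatives that left out IGKV5-43 reads or the libraries under 10000 reads, or counted YWQGTHFPRTF as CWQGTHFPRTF, were chosen after seeing the data, and the others beforehand. For single named features, TMM kept 163 calls or non-calls, ended 9 and added 8. DESeq2 kept 147, ended 15 and added 15, limma kept 154, ended 19 and added 7, and robust=FALSE kept 179, ended 0 and added 1. The replicate block kept 153, ended 44 and added 21, and no low-count filter kept 162, ended 18 and added 0. The 2 groups alone kept 126, ended 8 and added 14, leaving out IGKV5-43 reads kept 209, ended 21 and added 7, and leaving out libraries under 10000 reads kept 221, ended 16 and added 9. Distinct clonotypes kept 34, ended 15, added 5 and reversed 3, no thinning kept 13, ended 3, added 1 and reversed 1, and entries with at least 10 reads kept 72, ended 2 and added 1. Counting YWQGTHFPRTF as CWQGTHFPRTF kept 92 and reversed 1. Leaving out 1 library kept 2937, ended 215 and added 46, with 0 reversed. In simulated data 4-fold changes of clonotypes were mostly missed, and whether depth or spread between libraries causes this was not tested. A count of 0 allows shares of up to 0.0380% to 0.140% in the libraries under 10000 reads.

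Counts of clonotypes called between switched and unswitched thymic libraries (86) were 54 under TMM, 339 without a filter, 33 with the 2 groups alone, 36 with the replicate block and 147 without libraries under 10000 reads. For switched thymic and splenic libraries (112) they were 417 without a filter, 172 under limma and 199 without libraries under 10000 reads. For unswitched thymic and splenic libraries (22) they were 49 with DESeq2, 84 with the 2 groups alone, 91 with the block and 39 without libraries under 10000 reads, and Vκ genes (14) were 27 with the 2 groups alone and 25 with the block. More features are tested without a filter. For the other settings the cause was not tested.

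Counts of called shares were 1 (from 3), 7 (from 12) and 6 (from 11) by distinct clonotypes, in the order of comparisons, 1 and 6 for the first and the second without libraries under 10000 reads, and 4 for the second without IGKV5-43 reads. Called CDR3 features were 1 (from 2) in the first comparison by distinct clonotypes, 1 (from 2) in the second without libraries under 10000 reads, and 0, 0 and 0 (from 2 each) without IGKV5-43 reads. With the replicate block 0 shares and 0 CDR3 features were called in any comparison, and 0 diversity measures (from 6 and 1) in the comparisons with spleen. The smallest sign-flip p is 0.0625 with 5 pairs and 0.0156, before adjustment, with 7, so those zeros say little of stability. The block compares equal numbers, and the labels do not say that they pair the libraries. After centring by group, same-numbered thymic libraries correlated across clonotypes by 0.0526 to 0.172 (mean 0.120, other pairs -0.0199), 5 of 7 over 0.1. Of the unswitched 7 of 7 and of the switched 5 of 7 correlated best with their own number, a hint of pairing from the data and not the design, and 0 of 5 pairs with spleen were over 0.1. By Morisita-Horn similarity only 1 of 7 unswitched and 3 of 7 switched libraries were most similar to their own number. The cause of the other changes was not tested.

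Reversed were 5 differences. Between unswitched thymic and splenic libraries the IGKV4 family was 0.886, middle genes 0.412 and the modal CDR3 length 5.52 percentage points higher by distinct clonotypes. Between switched thymic and splenic libraries the Gini coefficient without thinning differed by -0.0661. The cause of these 4 was not tested. IGKV1-135 Jκ1 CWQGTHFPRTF, which fell from splenic to switched thymic libraries, had a log2 fold change of 0.46 (adjusted p = 0.690) with YWQGTHFPRTF reads added to it, most of them from switched library 1.

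With each library left out in turn, counts in the order of comparisons ranged over 64 to 126, 79 to 147 and 8 to 33 for clonotypes, 18 to 27, 18 to 26 and 11 to 16 for Vκ genes, and 3 to 6, 5 to 13 and 6 to 12 for shares. They were 1 to 3, 0 to 2 and 0 to 2 for CDR3 features, and 6 to 6, 5 to 6 and 0 to 4 for diversity. The excess similarity within groups was 0.296 to 0.383, and that of same-numbered thymic libraries 0.0116 to 0.0301, lowest without replicate 4 of either group, where it was no longer called.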

Other observations

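The test of Jκ2 within IGKV3-1 and those of the other Vκ-Jκ relations were chosen after the results they measure had been seen.

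The Jκ partners of some Vκ genes differed between switched and unswitched thymic libraries. Within IGKV3-1, Jκ2 made up 83.7% ± 10.4 of reads in switched and 30.3% ± 7.37 in unswitched libraries (SD, n = 7 each), and was higher in 7 of 7. Within IGKV5-39, the Jκ2 share was 26.9 percentage points higher in switched libraries, also in 7 of 7, and within IGKV3-4 the Jκ5 share was 22.1 points higher in 7 of 7. Within IGKV8-28 the Jκ4 share differed by -18.5 points, lower in 7 of 7. Over all genes together, no Jκ share differed between these groups by exact permutation test. Of the 32 relations tested (4 Jκ genes in the Vκ genes with the highest shares and IGKV5-43), 10 had an adjusted p under 0.05.

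One hypothesis is that cells with particular V-J junctions, rather than with a Vκ gene as such, may be enriched among switched thymic B cells. The difference in the Jκ2 share within IGKV3-1, 53.4 percentage points (exact permutation test, p = 0.000583, adjusted p = 0.00266 over the 32 relations), restates the rise of the clonotype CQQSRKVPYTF that prompted it and gives the hypothesis no support. That clonotype made up 67.1% to 94.5% of IGKV3-1 reads with Jκ2 in each switched library, and 72.1% ± 11.8 of all IGKV3-1 reads in switched against 24.6% ± 6.58 in unswitched libraries (SD, n = 7 each). Expansion of a few clones is not told apart from selection of a junction. The leading clonotype was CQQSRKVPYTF in switched libraries 4, 5 and 7, with 9.87%, 17.1% and 11.2% of reads, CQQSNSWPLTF of IGKV5-43 in libraries 2 and 3, with 45.9% and 14.1%, and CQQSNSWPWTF of IGKV5-43 in library 6 with 37.5%. In unswitched libraries 1 to 5 it was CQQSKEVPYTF of IGKV3-2 and Jκ2 (3.38%, 4.38%, 4.16%, 6.77% and 4.02%), in unswitched libraries 6 and 7 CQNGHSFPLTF of IGKV5-39 and Jκ5 (5.89% and 2.87%), and in all 5 splenic libraries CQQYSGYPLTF of IGKV4-57-1 and Jκ5 (4.23% to 9.29%).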
